A study of Caenorhabditis elegans with 15 samples.

How the data were processed

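RNA was sequenced from whole worms in 15 libraries, 3 in each of 5 groups named by the sample titles: TU3401 on luc RNAi and the glp-1 strain SHU47 on luc, hlh-30, atg-2 or atg-18 RNAi. Per the labels' protocols, worms were kept at 20 °C, RNAi was given by feeding bacteria of strain HT115(DE3) carrying L4440 vectors, samples were taken on adult day 1 in QIAZOL, and total RNA was purified on RNeasy columns before a standard Illumina library. Whether the libraries of a group came from separate cultures is not given in the sources used here.

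The authors deposited 4 tables of 42048 genes, each comparing 2 groups, with the 3 glp-1 luc columns repeated in each; 0 values differed between the copies of these columns, so the tables are on 1 scale. The expression values of each library are RPKM made by the authors, reads scaled by gene length and by the reads of the library, as the values themselves show: within a gene all values are whole multiples of a step per library. Whole reads were recovered from these steps for 24620 of 24620 detected genes (100.0%; relative tolerance 5e-13), although a gene's reads can come out divided by a common factor, and 94.34% of these genes gave a whole number of bases as length. Recovered depth was 17496595 to 25597189 reads per library (whether single reads or pairs is not given in the sources used here), and RPKM summed to 976822 to 1057684. A gene of 21 bases is worth 1.86 to 2.72 RPKM for a single read, so short genes pass the filter on few reads. Per the file headers, each deposited table also gives the authors' log2 fold change, the authors' unadjusted p-value with a false discovery rate, and a ranking score, which is the gene's rank by the authors' p-value; the test behind them is not given in the sources used here. The submitters' processing notes name bcl2fastq and TopHat2 2.1.1 and the human build GRCh38, which does not match gene names of C. elegans; the counting tool, the annotation and strand use are not given in the sources used here. No coordinates are therefore printed. The WBcel235 annotation was used only for current gene names, which matched 41146 of 42048 names (24001 of 24620 detected, 18731 of them protein coding), and for which genes neighbour each other.

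Tests were chosen before the data were examined, together with the groups, the 32 gene lists, the rule for named genes and most alternatives. The design foresaw count tables and gave a fallback for normalized values. Since the files hold RPKM, the test used was that fallback. It was limma 3.58.1 in R 4.3.3 with a mean-variance trend and without robust fitting on log2(RPKM + 1), over genes with a mean RPKM of at least 1 in the fit, with Benjamini-Hochberg adjusted p under 0.05 and changes in both directions counted. The design's wording left open whether the trend was on, so limma without it was added as an alternative. Comparisons with luc used the 6 libraries of the 2 groups, and direct contrasts between RNAi groups used the 12 glp-1 libraries in 1 fit. With 3 libraries against 3, an exact permutation of 1 gene cannot reach below 0.1, which is why no single-gene permutation test is given. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes; members were also counted with p adjusted over the list alone. The list of 14 genes of the mitochondrial genome is not analysed here, because 0 of its names were found. Named genes were hlh-30, atg-2, atg-18, glp-1, sid-1, mml-1 and mxl-2. To these were added, among called genes with a mean RPKM of at least 2 and groups that did not overlap, the 8 largest changes each way. Further ones were up to 2 called genes each way per list and, with fewer than 5 calls the 5 genes of smallest p. Other genes named as examples in lists without calls over all genes, and H02F09.3, were chosen after their values were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

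Libraries of a group were compared first: all 15 pairs within groups differed by more than sampling noise in their recovered reads (chi-square per degree of freedom 6.02 to 20.4, 0 pairs with identical values), so each counted as 1 replicate. The replicate numbers of the titles were checked for pairing by correlating deviations from the group means: for atg-2 RNAi and luc all 3 same-numbered pairs correlated (r across genes = 0.402, 0.264 and 0.200). So they did for hlh-30 and atg-2 RNAi (0.495, 0.276 and 0.286), for hlh-30 and atg-18 RNAi (0.207, 0.259 and 0.234) and for atg-2 and atg-18 RNAi (0.157, 0.196 and 0.190). This check of the direct contrasts was run after their blocked counts had been seen. Where all 3 pairs were over 0.1, the numbers were taken to pair the samples. There the blocked value stands beside the result if it changed the call. Libraries 1 of glp-1 luc, hlh-30 RNAi and atg-2 RNAi held more germline RNA, and whether this raised their correlations was not tested. In the direct contrasts the block covered all 12 libraries of the fit. These include luc, where 1 pair with hlh-30 RNAi (0.0690) and 1 with atg-18 RNAi (0.0841) lay under the bound. The chance level of shared calls and correlations between comparisons with the same glp-1 luc libraries was taken from 100 simulations in which all groups were unchanged. Germline RNA was followed by the median of 53 oocyte and germline core genes in each library as a percentage of TU3401.

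The steps were tested on simulated data for the comparison of hlh-30 RNAi with luc, with 68, 66 and 66 genes changed 1.5-fold, 2-fold and 4-fold among 12537 tested. Limma on log2 RPKM found 47.1% of genes changed 1.5-fold, 78.8% of those changed 2-fold and 95.5% of those changed 4-fold, and 23 of its 203 calls were false, a larger share than the nominal level. On recovered reads voom found 60.3%, 86.4% and 98.5% with 11 false of 206 calls, and limma with the block 17.6%, 65.2% and 97.0% with 17 false of 150. A list shifted 1.5-fold had a camera adjusted p of 5.64e-68 and of 0.00262 with an estimated correlation, and 0 of 29 unshifted lists passed. Reads were drawn independently for each gene and library, without correlation between genes or an effect shared by same-numbered libraries. The simulation therefore cannot show how often camera calls lists falsely in the real data, or what the block gains there. Read recovery was exact for 96.82% of 21026 simulated genes, and the ratios between libraries were exact for 100.0%.

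Alternatives set beforehand were scaling by median of ratios or on the pan-neuronal and muscle lists, a pseudocount of 0.1, no filter or a mean RPKM of at least 5. Others were all 15 libraries or only 2 groups in the fit, the replicate block, an absolute log2 change of at least 1, the other list tests, and leaving out each library in turn. Chosen after seeing the data were limma without the trend, voom on recovered reads with and without the block, a minimum of 10 mean reads, leaving out genes that fell by 2 or more with the loss of the germline, the block, the other list tests and the left-out libraries for lists in the direct contrasts, and leaving out the libraries numbered 1. Count tests that the design listed for integer tables were not run, and the recovered reads were tested with voom only. In 0 columns was the sample unclear.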

Results

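RNA was profiled by sequencing in 15 libraries of whole C. elegans on adult day 1, in 5 groups of 3. The first was TU3401, a strain that takes up feeding RNAi mainly in neurons because sid-1, the double-stranded RNA channel, is restored there in a sid-1 mutant, and it was fed bacteria with the control RNAi labelled luc. The other 4 groups were SHU47, labelled as glp-1 worms, which lack a germline and are long-lived, fed luc, hlh-30, atg-2 or atg-18 RNAi. Depth was 17496595 to 25597189 reads per library, as recovered from the steps of the deposited RPKM values. Values below are mean RPKM ± SD (n = 3 in every group), and changes are differences of log2(RPKM + 1), which understates the change of low genes. All tests across genes were limma with Benjamini-Hochberg adjustment. No label says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

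The RNAi targets were read first, because they check the labels. None was lower on average in the libraries labelled with its RNAi. hlh-30, the worm counterpart of the mammalian autophagy and lysosome regulator TFEB, stood at 54.6, 44.5 and 50.9 RPKM in the glp-1 luc libraries and at 126, 293 and 328 in the libraries labelled hlh-30 RNAi (50.0 ± 5.08 to 249 ± 108, a ratio of 4.98, higher in 3 of 3). On the log2 scale the difference was 2.18 ± 0.34 (SE) with limma adjusted p = 0.107. With each of the 6 libraries left out in turn it was 1.92 to 2.61 with adjusted p of 0.00405 to 0.307. It passed in 1 of these fits, the one without hlh-30 RNAi library 1. In the authors' deposited table it was 2.34 with a false discovery rate of 0.000215. hlh-30 lay between 41.8 and 55.4 in the 6 libraries of the other RNAi groups. atg-2, which encodes a lipid transfer protein of the growing autophagosome, went from 30.1 ± 4.19 to 40.2 ± 2.66 in the libraries labelled atg-2 RNAi (log2 difference 0.41, adjusted p = 0.434, higher in 3 of 3). atg-18, which encodes a phosphoinositide-binding partner of ATG-2, went from 72.5 ± 5.23 to 49.1, 81.3 and 116 in the libraries labelled atg-18 RNAi (0.10, adjusted p = 0.965); this difference was -0.19 without atg-18 RNAi library 3 and -0.015 when libraries were scaled on neuronal and muscle genes. Groups are therefore named throughout by their labels, and no direction below rests on a lowered target.

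**Figure D1:**
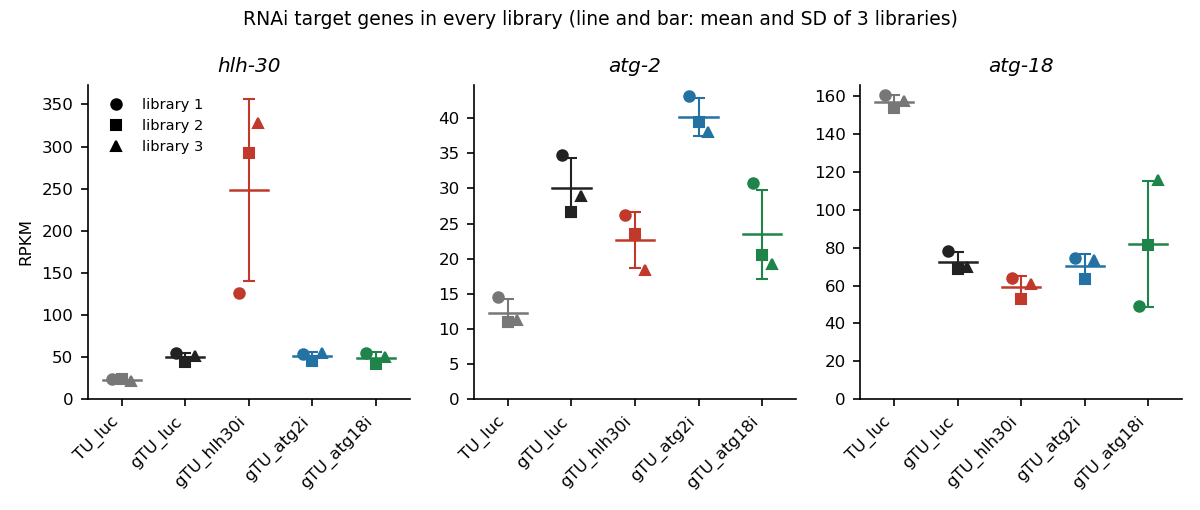
RPKM of the 3 RNAi targets in each of the 15 libraries by group, with the mean and SD of each group. hlh-30 was at 126 to 328 in the libraries labelled hlh-30 RNAi and at 41.8 to 55.4 in the other glp-1 libraries, and neither atg-2 nor atg-18 was lower on average in the libraries labelled with its RNAi.

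The comparison of glp-1 with TU3401 worms, both on luc, asked what the loss of the germline does to RNA of the whole animal. Maternal and germline transcripts nearly vanished. sip-1, a small heat shock protein of oocytes and embryos, went from 3173 ± 265 to 8.06 ± 12.9 (-9.65), and clec-87, a C-type lectin, from 2768 ± 65.1 to 8.5 ± 13.6 (-9.42). cey-2, a Y-box RNA-binding protein of the germline, went from 2431 ± 109 to 7.62 ± 11.43 (-9.09). The eggshell proteoglycan genes cpg-1 and cpg-2 changed by -9.05 and -8.80. iff-1, a germline translation factor, W05F2.3 and pos-1, a maternal zinc finger protein, changed by -8.98, -8.62 and -8.58. In the other direction far-3, a fatty acid and retinol binding protein, rose from 40.3 ± 7.28 to 3364 ± 150.3 (6.36) and F56D6.9 from 50.3 ± 32.6 to 5519 ± 520.0 (6.99). H39E23.3 rose from 0.0800 ± 0.0559 to 487 ± 57 (8.82) and scl-20, which encodes a secreted SCP-domain protein, from 0.0848 ± 0.0737 to 229.6 ± 54.4 (7.71). clx-1, dhs-26, which encodes a short-chain dehydrogenase, F56D6.8 and the collagen col-183 rose by 7.90, 7.10, 6.99 and 6.11. Adjusted p lay at or below 6.46e-05 for each of these genes, and the 3 libraries of each group lay on opposite sides for each. The large SD of the maternal genes among glp-1 luc libraries came with a difference in germline RNA: the median of 53 oocyte and germline genes was 1.03% of the TU3401 level in glp-1 luc library 1, 0.0983% in library 2 and 0.197% in library 3.

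Of 13569 genes tested, 12175 changed, 5615 of them higher and 6560 lower in glp-1 worms (46.1% higher), and 9409 of them by at least 1 on the log2 scale. The 3 libraries of the groups did not overlap for 12235 genes (90.2%, against 10% by chance). The authors' deposited table holds 13737 genes at a false discovery rate under 0.05, 11758 of them also called here and all of these in the same direction. The split depended on the scale: with libraries scaled on pan-neuronal and muscle genes, all changes shifted by a median of -1.31 and 17.8% of the called genes were higher. The 10 most abundant genes took 8.17% to 9.19% of reads in TU3401 and 18.8% to 21.5% in the glp-1 libraries. List directions below are therefore given with the list's median or counts under that scaling.

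Germline and cell division lists fell as blocks. All 38 germline core genes fell (median -4.86, -5.91 when scaled on neuronal and muscle genes; camera adjusted p = 1.78e-08, adjusted p = 0.385 with an estimated correlation), among them syp-2, a synaptonemal complex gene (83.8 ± 1.81 to 0.941 ± 0.214), and car-1, a germ granule RNA-binding protein (-4.29). All 40 cell cycle genes fell (median -5.47, -6.59 scaled; camera adjusted p = 1.78e-08, adjusted p = 0.455 with an estimated correlation), such as cye-1, which encodes cyclin E (-5.25), and sas-6, a centriole gene (-4.34). In the oocyte list 24 of 26 fell (median -7.71, -8.72 scaled; camera adjusted p = 6.05e-04, adjusted p = 0.596 with an estimated correlation), with lin-41 and pie-1 at -5.78 and -5.03, while the eggshell genes perm-2 and perm-4 rose by 1.23 and 1.40, but stood at -0.24 and -0.067 when scaled. Of 12 genes of early embryonic transcription 11 fell and 1, sdz-24, rose (median -2.33, -2.96 scaled; camera adjusted p = 0.0210, adjusted p = 0.362 with an estimated correlation; 0.118 in camera when scaled and 0.261 among genes with a mean RPKM of at least 5). Of 6 measured sperm genes 2 rose and 4 fell (camera adjusted p = 0.643), and 1 rose and 4 fell when scaled (median -2.02). In every list of this comparison, the counts adjusted over the list alone were equal to those over all genes.

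**Figure D2:**
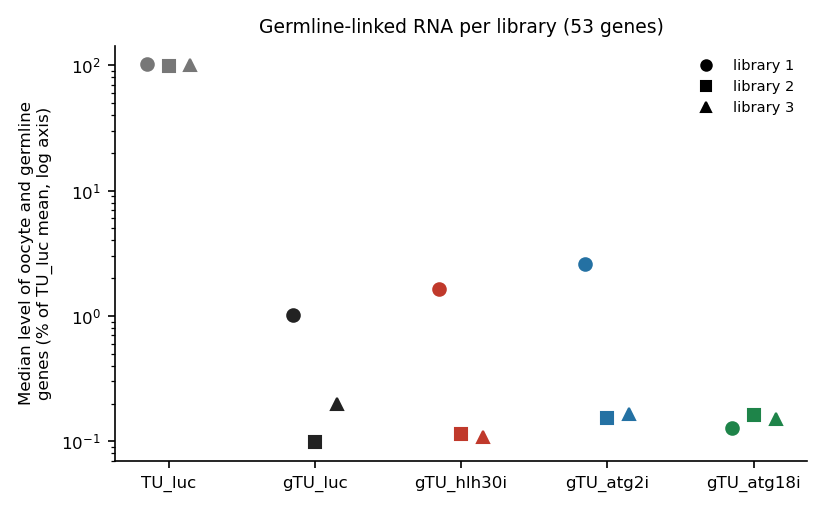
Median RPKM of 53 oocyte and germline core genes in each library, as a percentage of the TU3401 mean, on a log axis by group. The libraries numbered 1 of glp-1 luc, hlh-30 RNAi and atg-2 RNAi sat at 1.03%, 1.64% and 2.59%, and the other 9 glp-1 libraries at 0.0983% to 0.197%.

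RNA of growth and protein turnover machinery also fell. In whole worms these falls cannot be told apart from the loss of the germline's own RNA. Scaling on neuronal and muscle genes does not part the 2 either. All 32 proteasome genes fell (median -2.01, -3.46 scaled; camera adjusted p = 5.80e-08, adjusted p = 0.385 with an estimated correlation), for example the ATPase subunit genes rpt-1 (-2.34) and rpt-5 (-2.24). Of 78 ribosomal protein genes 76 fell (median -1.01, -2.48 scaled; camera adjusted p = 4.95e-08, adjusted p = 0.587 with an estimated correlation). Paralogous ribosomal genes parted: rpl-11.1 went from 2454 ± 234 to 25 ± 11 and rpl-25.2 fell by 2.92, while rpl-11.2 and rpl-25.1 rose by 1.29 and 1.53. Near-identical copies can share reads, which makes these values uncertain, and rpl-11.2 stood at -0.17 when scaled. Of 35 small RNA genes 28 fell, among them mut-2 (-3.67) and eri-1 (-3.14), and 5 rose, among them sago-1 (1.85) and sid-2 (1.79) (median -1.83, -3.18 scaled; camera adjusted p = 0.00107, adjusted p = 0.385 with an estimated correlation). Mitochondrial chaperone and stress genes fell in 14 of 18 cases, such as hsp-6 (-2.09) and phb-2 (-2.18; median -1.37, -2.81 scaled; camera adjusted p = 0.0325, adjusted p = 0.385 with an estimated correlation). They rose in 3, among them gpd-2 (2.34), a glycolytic enzyme, and among genes with a mean RPKM of at least 5 camera p was 0.0737.

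Neuropeptide, insulin, immune and DAF-16 lists had medians above 0 under both scales, though fewer genes rose when scaled. All 54 neuropeptide genes rose (median 1.64, 0.26 scaled, where 20 rose and 2 fell; camera adjusted p = 7.90e-12, adjusted p = 0.329 with an estimated correlation), for example flp-28 (64.8 ± 1.84 to 299 ± 7.29) and nlp-40 (2.22). Of 22 genes raised by the FOXO factor DAF-16 in long-lived worms 21 rose and 1, sip-1, fell (median 3.04, 1.59 scaled, where 19 rose and 1 fell; camera adjusted p = 6.20e-07, adjusted p = 0.329 with an estimated correlation), with icl-1, a glyoxylate cycle enzyme, going from 71.5 ± 2.61 to 478 ± 17.7. Immune genes rose in 37 and fell in 2 of 52 cases (median 1.74, 0.43 scaled, where 24 rose and 10 fell; camera adjusted p = 6.65e-07, adjusted p = 0.385 with an estimated correlation), with the lysozyme lys-2 at 2.74 and the lectin clec-63 at 2.14. Insulin-like peptide genes rose in 20 and fell in 2 of 24 cases (median 1.46, 0.21 scaled, where 8 rose and 4 fell; camera adjusted p = 5.01e-04, adjusted p = 0.329 with an estimated correlation), with ins-19 and ins-27 at 4.17 and 2.61 and ins-34 at -4.0. Lipase and lipid genes rose in 29 and fell in 9 of 39 cases (median 1.5, 0.039 scaled, where 15 rose and 16 fell; camera adjusted p = 5.84e-05, adjusted p = 0.329 with an estimated correlation), with the lysosomal lipase lipl-2 going from 13.4 ± 0.98 to 134 ± 5.57 and the lipid droplet lipase atgl-1 changing by -2.02.

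Somatic tissue lists were higher on the RPKM scale, but had scaled medians below 0. Muscle genes rose in 32 and fell in 4 of 36 cases (median 1.39, -0.049 scaled, where 15 rose and 12 fell), with mlc-1 and atn-1 at 1.93 and 1.81. Their camera adjusted p was 5.23e-06, and 0.385 with an estimated correlation. The muscle list is part of the scaling, which holds its scaled median near 0. Intestinal genes rose in 21 and fell in 3 of 25 cases (median 1.14, -0.22 scaled, where 7 rose and 11 fell; camera adjusted p = 1.38e-04, adjusted p = 0.329 with an estimated correlation), with ftn-2, which encodes ferritin, at 1.76. Lysosomal genes rose in 34 and fell in 5 of 42 cases (median 0.67, -0.79 scaled, where 8 rose and 25 fell; camera adjusted p = 9.66e-06, adjusted p = 0.329 with an estimated correlation), with the aspartyl protease asp-3 going from 565 ± 40.4 to 3123 ± 57.4 and cup-5, a lysosomal channel, changing by -2.35. The median was also below 0 when scaled for hypodermal genes (16 rose and 6 fell of 22; 1.02, -0.39 scaled, where 6 rose and 12 fell; camera adjusted p = 0.0180, adjusted p = 0.329 with an estimated correlation). So it was for transmitter-specific neuron genes (14 rose and 3 fell of 20; 0.76, -0.18 scaled, where 4 rose and 6 fell; camera adjusted p = 0.0130, adjusted p = 0.455 with an estimated correlation). It was for detoxification genes as well (19 rose and 7 fell of 29; 1.32, -0.087 scaled, where 12 rose and 12 fell; camera adjusted p = 0.0107, adjusted p = 0.329 with an estimated correlation). The same was found for peroxidases (13 rose and 5 fell of 19; 0.95, -0.48 scaled, where 4 rose and 10 fell; camera adjusted p = 0.0234, adjusted p = 0.329 with an estimated correlation), and for the yolk protein genes (5 rose and 0 fell of 6; 1.22, -0.25 scaled, where 1 rose and 3 fell; camera adjusted p = 0.0165, adjusted p = 0.455 with an estimated correlation). vit-5 went from 3156 ± 293 to 10002 ± 903, and vit-2 rose by 1.40 but stood at -0.072 when scaled. Among transmitter genes, tdc-1, the tyrosine decarboxylase of tyramine and octopamine synthesis, fell from 123 ± 5.75 to 4.70 ± 0.408, and tbh-1, which makes octopamine from tyramine, rose from 128 ± 9.60 to 860.1 ± 20.9. Scaled camera p-values were 0.307 for the lysosome, 0.114 for the hypodermis, 0.261 for peroxidases and 0.487 for yolk proteins.

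The other 10 measured lists did not pass camera. Of 28 autophagy genes 5 rose and 19 fell (median -0.84, -2.28 scaled; adjusted p = 0.0818), with sepa-1 and epg-2, whose products are cleared by autophagy in embryos, at -4.53 and -4.14 and sqst-1, the worm p62, at 1.18 but at -0.27 when scaled. Of 100 collagens 49 rose and 44 fell, with a median of 0.45, a mean of -0.064 and camera pointing up (adjusted p = 0.0816); the scaled median was -0.80. col-139 and col-36 were at 5.0 and 4.45, and dpy-7 and dpy-3 at -4.15 and -4.08. Camera adjusted p was 0.0643 for pan-neuronal genes (17 rose and 7 fell of 32, median 0.59). Scaled, 3 of them rose and 18 fell (median -0.59), although this list is part of the scaling, which uses summed RPKM. Camera adjusted p was 0.377 for endoplasmic reticulum chaperones (4 and 11 of 20, 0 and 20 scaled). It was 0.648 for cytosolic chaperones (6 and 9 of 15, 1 and 10 scaled). For the respiratory chain it was 0.477 (8 and 22 of 39, 0 and 35 scaled). Moulting genes were at 0.235 (7 and 18 of 26, 2 and 20 scaled). Coelomocyte and somatic gonad genes were at 0.134 (11 and 6 of 19, 3 and 10 scaled). Regulators studied in worms without a germline were at 0.799 (8 and 11 of 22, 4 and 16 scaled). In that last list daf-12 and nhr-80 rose by 1.73 and 2.01, tcer-1 changed by -2.07, and mxl-2, the partner of MML-1, went from 65.8 ± 2.15 to 18.8 ± 0.574 (-1.76). mml-1 did not pass the test (10.5 ± 0.688 to 10.2 ± 1.83, adjusted p = 0.747). glp-1, which encodes the germline Notch receptor, went from 69.6 ± 3.53 to 2.96 ± 0.426 (-4.16). hlh-30 rose from 23.2 ± 1.46 to 50.0 ± 5.08 (1.07), atg-2 by 1.23 and sid-1 by 0.43, but scaled on neuronal and muscle genes these stood at -0.35, -0.16 and -1.02. atg-18 fell by 1.11.

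**Figure D3:**
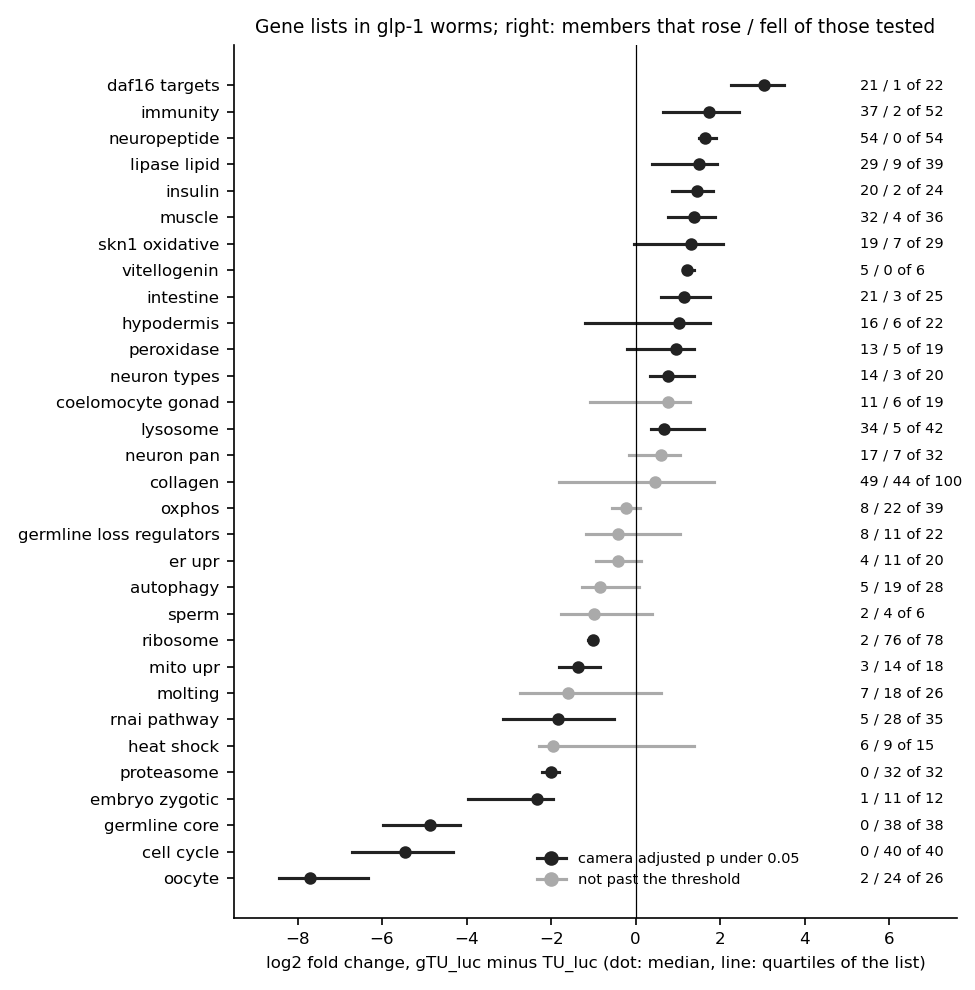
Median and quartiles of the log2 change from TU3401 to glp-1 (both on luc) for each fixed gene list, with the numbers of genes that rose and fell, in black where camera passed and grey where it did not. The germline core, cell cycle and oocyte lists had medians of -4.86, -5.47 and -7.71. Scaled on neuronal and muscle genes, medians turned negative for pan-neuronal, muscle, intestine, lysosome, hypodermis, neuron type, detoxification, peroxidase, yolk, collagen and coelomocyte lists.

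The libraries labelled hlh-30 RNAi were next compared with glp-1 luc, the question being what HLH-30 does in neurons of long-lived worms. Transcripts that fell there were led by tts-1, a long noncoding RNA abundant in long-lived worms (2437 ± 373 to 403 ± 116, -2.63, adjusted p = 0.0182), and dct-8 (638 ± 180.2 to 63.4 ± 24.9, -3.35, adjusted p = 0.0354), a gene named for its control by DAF-16. cpr-4, a cathepsin B-like protease, fell from 216 ± 30.3 to 102 ± 8.99 (-1.07, adjusted p = 0.0378), spp-2, a saposin-like protein, from 1767 ± 162 to 919 ± 94.4 (-0.94, adjusted p = 0.0354) and T24F1.5, now named nlp-51, from 74.2 ± 6.01 to 38.5 ± 0.953 (-0.92, adjusted p = 0.0182). Y105C5B.5 (-1.02), Y43F8B.9 (-1.56) and T05E12.3 (-0.80) fell as well. grd-14, a hedgehog-related gene, was the only gene called higher by limma on log2 RPKM (57 ± 5.34 to 106 ± 6.53, 0.88, adjusted p = 0.0354). Each of these genes moved in 3 of 3 libraries.

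Limma called 11 of 12494 genes, 1 higher and 10 lower, with 1187 at an unadjusted p under 0.05; the groups did not overlap for 14.5% of genes, against 10% by chance. The other 2 called genes were 21ur-1893 and 21ur-784, which encode 21-base piRNAs and held at most 2 reads in any library. The authors' deposited table lists 93 genes, 23 higher and 70 lower, and 9 genes were called in both, with the same sign; tts-1 and dct-8 have false discovery rates of 3.47e-07 and 9.12e-07 in the authors' deposited table. The calls depended on single libraries: 11, 11 and 0 genes were called without glp-1 luc library 1, 2 or 3, and 3, 0 and 0 without hlh-30 RNAi library 1, 2 or 3. The fold change of tts-1 stayed between -2.82 and -2.39 and that of dct-8 between -3.62 and -3.02 in these 6 fits, with adjusted p up to 0.0933 and 0.145. Other settings without a replicate block gave between 1 gene (both libraries numbered 1 left out, where that gene was higher) and 56 genes (all 15 libraries in the fit). With the block limma called 46 genes and voom on recovered reads 399. Here 1 of the same-numbered pairs correlated at 0.0690, under the bound of 0.1 for pairing. mxl-2 was at 18.8 ± 0.574 to 12.57 ± 0.746 (-0.55, adjusted p = 0.0819) and mml-1 at 10.2 ± 1.83 to 8.33 ± 0.670 (-0.26, adjusted p = 0.593); neither passed. atg-18, atg-2, sid-1 and glp-1 did not pass either (-0.29, -0.40, -0.032 and 0.027).

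Of the fixed lists, 7 passed camera in this comparison, while 0 passed with an estimated correlation (each adjusted p at or above 0.917) and 0 passed fry. Cuticle collagens were higher (15 rose and 1 fell of 78 when adjusted over the list alone, 0 over all genes; camera adjusted p = 2.74e-11, adjusted p = 0.917 with an estimated correlation), for example rol-8 (8.88 ± 0.428 to 12.9 ± 0.780, 0.49) and col-98 (0.39). Autophagy genes were lower, with 5 of 27 falling when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00437, adjusted p = 0.955 with an estimated correlation, and 0.0698 in camera without glp-1 luc library 1). lgg-1, the worm LC3 relative of the autophagosome membrane, was at 1820.2 ± 121 to 1312 ± 73.0 (-0.47) and lgg-2 at 261 ± 20.3 to 205 ± 12.7 (-0.35). Cytosolic chaperones were lower, with 0 of 15 passing over the list alone or over all genes and 7 at an unadjusted p under 0.05 (camera adjusted p = 1.87e-04, adjusted p = 0.917 with an estimated correlation; 0.0695 in camera without germline-linked genes, a setting chosen after seeing the data). dnj-13 was at 50.1 ± 13.6 to 25.8 ± 8.54 and hsp-1 at 303 ± 38.1 to 202 ± 60.7. In the lysosome list, which did not pass (adjusted p = 0.124), 3 of 42 fell when adjusted over the list alone, cpr-4, cpr-1 (187 ± 57 to 75.8 ± 5.53) and nuc-1 (-0.25), and 1 over all genes. In the immunity list 5 rose and 4 fell of 51 when adjusted over the list alone (camera adjusted p = 0.837). Detoxification, muscle and respiratory chain genes passed camera as higher (adjusted p = 0.0119, 0.00437 and 0.0400; 0.917, 0.955 and 0.955 with an estimated correlation), with 0 members called by limma over the list alone and 8 (6 higher and 2 lower), 0 and 0 at an unadjusted p under 0.05. Without glp-1 luc library 1 their camera p-values were 0.093, 0.73 and 0.913, and without hlh-30 RNAi library 2 they were 0.161, 0.571 and 0.876; the respiratory chain list pointed down without glp-1 luc library 1. Without the libraries numbered 1 the first and last were at 0.0744 and 0.167, and scaled on neuronal and muscle genes the last 2 were at 0.122 and 0.982. Ribosomal protein genes passed as lower (camera adjusted p = 0.0404, adjusted p = 0.955 with an estimated correlation; 0.921, 0.981 and 0.329 without glp-1 luc library 2, glp-1 luc library 3 or hlh-30 RNAi library 1), with a median of -0.038, and pointed up without either of the last 2. It was at 0.0659 without germline-linked genes and 0.0934 among genes with a mean RPKM of at least 5. The lists of oocyte, germline core and cell cycle genes did not pass (adjusted p = 0.483, 0.837 and 0.643), where hlh-30 RNAi library 1 held germline RNA at 1.64% of the TU3401 level and libraries 2 and 3 held 0.115% and 0.109%.

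The libraries labelled atg-2 and atg-18 RNAi were compared with glp-1 luc to see what these autophagy genes do in the same neurons. Limma called 0 of 12548 genes for atg-2 RNAi, with 961 at an unadjusted p under 0.05, a smallest adjusted p of 0.434 and 13.4% of genes without overlap between the groups (10% by chance). The 5 genes with the smallest p, none of which passed, were cpt-4, a carnitine palmitoyltransferase (1.04 ± 0.157 to 3.51 ± 0.632), gba-2, a glucosylceramidase (1.79 ± 0.656 to 5.37 ± 0.385), srw-86, a chemoreceptor (13 ± 2.80 to 5.15 ± 0.940), and the piRNA genes 21ur-4139 and 21ur-684, both listed at 0 in all glp-1 luc libraries. The authors' deposited table holds 2 genes, cpt-4 (1.76, false discovery rate 0.0218) and H02F09.3 (-1.78, 0.0441). For this comparison the replicate numbers were taken to pair the samples. The block left limma at 0 genes, while voom on recovered reads gave 0 without the block and 596 with it. The 15-library fit gave 2 genes and limma without the trend gave 1.

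For atg-2 RNAi 14 lists passed camera, while 0 passed with an estimated correlation (each adjusted p at or above 0.511) or in fry, and limma called 0 list members over all genes. With the replicate block autophagy genes passed as well, as lower (camera adjusted p = 0.0295, and 0.129 without the block; adjusted p = 0.614 with the block and an estimated correlation). Immune genes were lower, with 1 rising and 10 falling of 51 when adjusted over the list alone (camera adjusted p = 2.97e-04, adjusted p = 0.511 with an estimated correlation). clec-63 was at 3676 ± 121.97 to 3050.0 ± 77.3 and the lectin clec-67 at 229.5 ± 14.9 to 153 ± 20.6, while spp-1, a saposin-like antimicrobial protein, was at 849 ± 116 to 1242 ± 111. Also lower were endoplasmic reticulum chaperones such as hsp-4, the worm BiP (300.3 ± 82.6 to 205 ± 28.8; camera adjusted p = 1.10e-05, adjusted p = 0.511 with an estimated correlation). Intestinal genes (camera adjusted p = 3.56e-04, adjusted p = 0.511 with an estimated correlation) and cytosolic chaperones (camera adjusted p = 0.00207, adjusted p = 0.511 with an estimated correlation; 0.137 in camera without germline-linked genes) were lower too. So were lysosomal genes such as asp-6 (3425 ± 512 to 2526 ± 63.2; camera adjusted p = 0.00157, adjusted p = 0.511 with an estimated correlation; 0.0751 in camera without atg-2 RNAi library 1). Ribosomal protein genes were higher by a median of 0.068 (camera adjusted p = 2.04e-13, adjusted p = 0.511 with an estimated correlation). Neuropeptide genes were higher (camera adjusted p = 9.05e-04, adjusted p = 0.511 with an estimated correlation; 0.0504 in camera scaled on neuronal and muscle genes), and so were insulin genes such as ins-18 (9.87 ± 1.61 to 14.3 ± 1.5; camera adjusted p = 0.00105, adjusted p = 0.511 with an estimated correlation). Respiratory chain, muscle and yolk genes passed as higher (camera adjusted p = 1.13e-04, 0.00207 and 0.0110; adjusted p = 0.649, 0.812 and 0.511 with an estimated correlation). Their camera p-values were 0.299, 0.826 and 0.148 without glp-1 luc library 1 and 0.272, 0.906 and 0.272 without atg-2 RNAi library 2, and the first 2 were at 0.0706 and 0.102 when scaled. DAF-16 targets passed as higher (camera adjusted p = 0.0147, adjusted p = 0.511 with an estimated correlation; 0.0862 and 0.0852 without glp-1 luc library 2 or atg-2 RNAi library 1, and 0.120 without the libraries numbered 1). Cell cycle and oocyte genes passed as higher (camera adjusted p = 0.0110 and 0.0471; adjusted p = 0.849 and 0.849 with an estimated correlation), where atg-2 RNAi library 1 held germline RNA at 2.59% of the TU3401 level and libraries 2 and 3 held 0.153% and 0.166%. Without that library both lists pointed down (0.263 and 0.0852), and without glp-1 luc library 2 or 3 they had p-values of 0.154 and 0.0867 (cell cycle) and 0.292 and 0.258 (oocyte). They were at 0.737 each without the libraries numbered 1, and at 0.199 and 0.106 among genes with a mean RPKM of at least 5. Over the list alone limma called 1 gene in each of the lysosome and sperm lists and 0 in the lists not given a count.

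For atg-18 RNAi limma called 0 of 12441 genes, with 850 at an unadjusted p under 0.05 and 11.8% of genes without overlap between the groups (10% by chance). R08F11.4 (11.5 ± 1.55 to 27.8 ± 1.77, 1.21) and hmp-2, the beta-catenin of epidermal junctions (12.7 ± 1.79 to 28.7 ± 2.05, 1.12), had the smallest adjusted p of 0.0633, with the piRNA genes 21ur-1893 and 21ur-5862, both listed at 0 in all libraries labelled atg-18 RNAi. F41E6.12, the annotated neighbour of atg-18 on the same strand, was at 20.7 ± 2.82 to 9.24 ± 1.13 (-1.08, adjusted p = 0.168), lower in 3 of 3. The authors' deposited table lists 44 genes, 8 higher and 36 lower, with false discovery rates of 1.42e-06 for hmp-2, 5.89e-06 for R08F11.4 and 0.000247 for F41E6.12. The 15-library fit gave 3 genes, voom on recovered reads 2 and limma without the trend 1. With the replicate block limma called 0 genes and voom 457. Here 1 of the same-numbered pairs correlated at 0.0841, under the bound of 0.1 for pairing. hlh-30, mxl-2 and mml-1 did not pass for atg-2 RNAi (0.039, -0.10 and -0.068) or for atg-18 RNAi (-0.030, -0.10 and -0.14).

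Endoplasmic reticulum chaperones were lower for atg-18 RNAi, as they were for atg-2 RNAi (for atg-18 RNAi camera adjusted p = 3.06e-07, adjusted p = 0.913 with an estimated correlation). For atg-18 RNAi 7 of 20 fell when adjusted over the list alone and 0 over all genes. Among them were the protein disulfide isomerases pdi-2 (524 ± 51.5 to 407 ± 8.57) and pdi-6 (285 ± 30.5 to 218 ± 5.06) and the calreticulin crt-1 (879.7 ± 152 to 625 ± 44.2). In all, 9 lists passed camera, and 0 passed with an estimated correlation or in fry. Cytosolic chaperones were lower (camera adjusted p = 0.00148, adjusted p = 0.913 with an estimated correlation; 0.133 in camera without germline-linked genes). So were intestinal genes such as gtl-1 (12.8 ± 1.81 to 8.53 ± 0.555; camera adjusted p = 0.00148, adjusted p = 0.913 with an estimated correlation; 0.0543 in camera without atg-18 RNAi library 1). Immune genes were lower, with 1 of 50 falling over the list alone (camera adjusted p = 0.00539, adjusted p = 0.913 with an estimated correlation; 0.114 and 0.0684 without glp-1 luc library 3 or atg-18 RNAi library 2, and 0.0738 when scaled on neuronal and muscle genes). Respiratory chain, ribosomal and muscle genes passed as higher (camera adjusted p = 5.07e-04, 5.48e-04 and 0.00539; adjusted p = 0.913 for each with an estimated correlation). Their camera p-values were 0.568, 0.856 (pointing down) and 0.893 without glp-1 luc library 1 and 0.324, 0.65 and 0.54 without atg-18 RNAi library 2. Scaled on neuronal and muscle genes the ribosomal list pointed down (0.142), and the respiratory chain and muscle lists were at 0.532 and 0.356. Neuropeptide genes passed as higher (camera adjusted p = 0.0125, adjusted p = 0.913 with an estimated correlation; 0.0543 without atg-18 RNAi library 1 and 0.356 when scaled). Insulin genes passed as higher too (camera adjusted p = 0.0367, adjusted p = 0.913 with an estimated correlation), although over the list alone 0 rose and 1 fell, with p-values of 0.224 and 0.0781 without glp-1 luc library 1 or 3 and 0.0649 and 0.191 without atg-18 RNAi library 2 or 3, and of 0.303 among genes with a mean RPKM of at least 5. The number of lists was 5, 15 and 12 without glp-1 luc library 1, 2 or 3, and 4 when scaled on neuronal and muscle genes.

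The RNAi groups were also set directly against each other in 1 fit of 12 glp-1 libraries. The libraries labelled hlh-30 RNAi parted from both autophagy groups in tts-1, dct-8 and cpr-4: the changes against atg-2 RNAi and against atg-18 RNAi were -2.65 and -2.78 for tts-1, -3.57 and -3.79 for dct-8 and -1.28 and -1.25 for cpr-4. cpr-1, another cathepsin B-like protease, was at 215 ± 26.7 for atg-2 RNAi, 246 ± 4.66 for atg-18 RNAi and 75.8 ± 5.53 for hlh-30 RNAi, with 187 ± 57 for luc (-1.49 and -1.69, adjusted p = 0.00245 and 7.66e-04). The lysosomal lipase lipl-1 was at 31.9 ± 1.77, 29.7 ± 2.06 and 14.1 ± 2.17 (-1.13 and -1.03, adjusted p = 0.00119 and 0.00128). lgg-1 was at 1761 ± 114, 1827 ± 220.1 and 1312 ± 73.0 (-0.42 and -0.47, adjusted p = 0.0481 and 0.0321). The antimicrobial peptide gene nlp-28 fell as well (-2.23 and -1.89). Higher than in both autophagy groups were hlh-30 itself (2.14 and 2.21, adjusted p = 0.00645 and 0.00511) and the hedgehog-related genes grd-3 and grd-5 (0.47 and 0.47 against atg-2 RNAi). dod-21, an infection-response gene, B0024.4 and the lectin clec-41 parted as well, but there the autophagy groups were on average the ones farther from luc. dod-21 was at 386, 137 and 113 in the glp-1 luc libraries, 259 ± 30.2 for hlh-30 RNAi, 45.7 ± 7.44 for atg-2 RNAi and 56.5 ± 15.4 for atg-18 RNAi (adjusted p = 0.0125 and 0.0242 for the direct contrasts). B0024.4 was at 381, 211 and 150.2 for luc and, in the same order of RNAi groups, at 389 ± 45.5, 96.9 ± 15.5 and 104.1 ± 34.4. Its order of distances from luc leans on luc library 1, the only luc library near the hlh-30 RNAi mean. clec-41 was at 904 ± 227 for luc and at 993 ± 65.2, 550.1 ± 26.1 and 569 ± 46.6. Against luc limma called none of these 3 genes in any RNAi group, while the authors' deposited table has -1.88 (false discovery rate 0.00524) for dod-21, -1.23 (0.0234) for B0024.4 and -0.65 (0.0198) for clec-41 with atg-18 RNAi. With each of the 6 libraries of a pair left out in turn, tts-1, dct-8, cpr-1, cpr-4, lipl-1 and hlh-30 passed in all 6 fits of both contrasts, whereas nlp-28 passed in 4 and 1, dod-21 in 4 and 0 and B0024.4 in 2 and 1. lgg-1 passed in 0 and 1, clec-41 in 1 and 0, grd-3 in 5 and 1 and grd-5 in 6 and 1.

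Limma called 126 genes between hlh-30 and atg-2 RNAi (72 higher and 54 lower for hlh-30 RNAi) and 127 between hlh-30 and atg-18 RNAi (58 and 69), with 1561 and 1245 at an unadjusted p under 0.05. By the bound of 0.1 the replicate numbers were taken to pair the samples in these contrasts. With the number as a block the counts were 757 (385 higher and 372 lower) and 506 (251 higher and 255 lower). With the block atg-2 passed as lower for hlh-30 than for atg-2 RNAi (-0.81, adjusted p = 0.00346). So did mxl-2 for hlh-30 RNAi in both contrasts (-0.44 and -0.45, adjusted p = 0.0192 and 0.0224). Without library 1, 2 or 3 the counts were 42, 59 and 30 (atg-2 RNAi) and 68, 86 and 34 (hlh-30 RNAi) for the first contrast. They were 28, 78 and 30 (atg-18 RNAi) and 41, 58 and 31 (hlh-30 RNAi) for the second, and 46 with only its own 2 groups in the fit. Collagens rose in 6 and 4 of 81 cases over all genes, and in 14 and 8 over the list alone, where 1 and 0 fell. Camera adjusted p was 1.35e-05 for the first contrast and 5.87e-08 for the second (adjusted p = 0.776 and 0.860 with an estimated correlation). Immune genes rose in 7 and fell in 3 of 51 cases against atg-2 RNAi and rose in 2 and fell in 2 against atg-18 RNAi, over all genes. Over the list alone 15 rose and 8 fell in the first and 10 and 7 in the second (camera adjusted p = 0.0128 and 0.0458; adjusted p = 0.776 and 0.860 with an estimated correlation). The second did not pass camera without atg-18 RNAi library 2 or 3 (0.0950 and 0.108) or hlh-30 RNAi library 1 or 3 (0.0713 and 0.0791). In the lysosome list 3 and 5 of 42 fell over all genes, and 7 and 6 over the list alone, where 3 and 0 rose. That list did not pass camera: against atg-2 RNAi it pointed up (adjusted p = 0.314) with a median of 0.072 and a mean of -0.024, and against atg-18 RNAi down (0.449) with a median of 0.018 and a mean of -0.071. In all, 7, 7 and 5 lists passed camera in the 3 direct contrasts, and 0 passed with an estimated correlation or in fry. With the block 9, 9 and 6 passed camera. The added ones were cytosolic chaperones and regulators of germline loss as lower for hlh-30 than for atg-2 RNAi (camera adjusted p = 0.0130 and 0.0376; adjusted p = 0.480 for each with an estimated correlation). Others were cell cycle genes as higher and yolk protein genes as lower for hlh-30 than for atg-18 RNAi (0.0186 and 0.00980; adjusted p = 0.769 and 0.599 with an estimated correlation). In that contrast hlh-30 RNAi library 1 held germline RNA at 1.64% of the TU3401 level, and the atg-18 RNAi libraries held 0.126% to 0.163%. Endoplasmic reticulum chaperones passed as higher for atg-2 than for atg-18 RNAi (0.0110; adjusted p = 0.763 with an estimated correlation). The ribosomal list was lower for hlh-30 RNAi than for atg-2 and atg-18 RNAi (camera adjusted p = 6.37e-16 and 2.40e-10; adjusted p = 0.776 and 0.860 with an estimated correlation; 0.0713 in camera for the second without hlh-30 RNAi library 1). Between atg-2 and atg-18 RNAi limma called 2 genes, F41E6.12, higher by 1.11 for atg-2 RNAi, and hmp-2 (-1.11; adjusted p = 0.0171 for both, 3 of 3 libraries), with 391 at an unadjusted p under 0.05. It called 0 with only these 2 groups in the fit, 0 without each of the 3 atg-18 RNAi libraries in turn, and 2, 0 and 1 without atg-2 RNAi library 1, 2 or 3. In these 6 fits F41E6.12 passed in 0 (adjusted p = 0.0664 to 0.107) and hmp-2 in 1 (0.0394 to 0.107). F23A7.5, named here after its values were seen, passed in 2 of them (adjusted p = 0.0572 with all libraries). Between hlh-30 and atg-2 RNAi limma called it (-4.93, adjusted p = 0.00688), and it passed there in 6 of 6 left-out fits (-5.86 to -3.99). Between hlh-30 and atg-18 RNAi, F41E6.12 and hmp-2 each passed in 6 of 6 left-out fits. Their changes there were 1.38 to 1.56 and -1.43 to -1.25, with limma adjusted p up to 0.00369 and 0.00497. In the contrast of atg-2 with atg-18 RNAi, hmp-2 was the 1 gene called with the block (adjusted p = 0.00115). F41E6.12 did not pass there (0.0639).

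**Figure D4:**
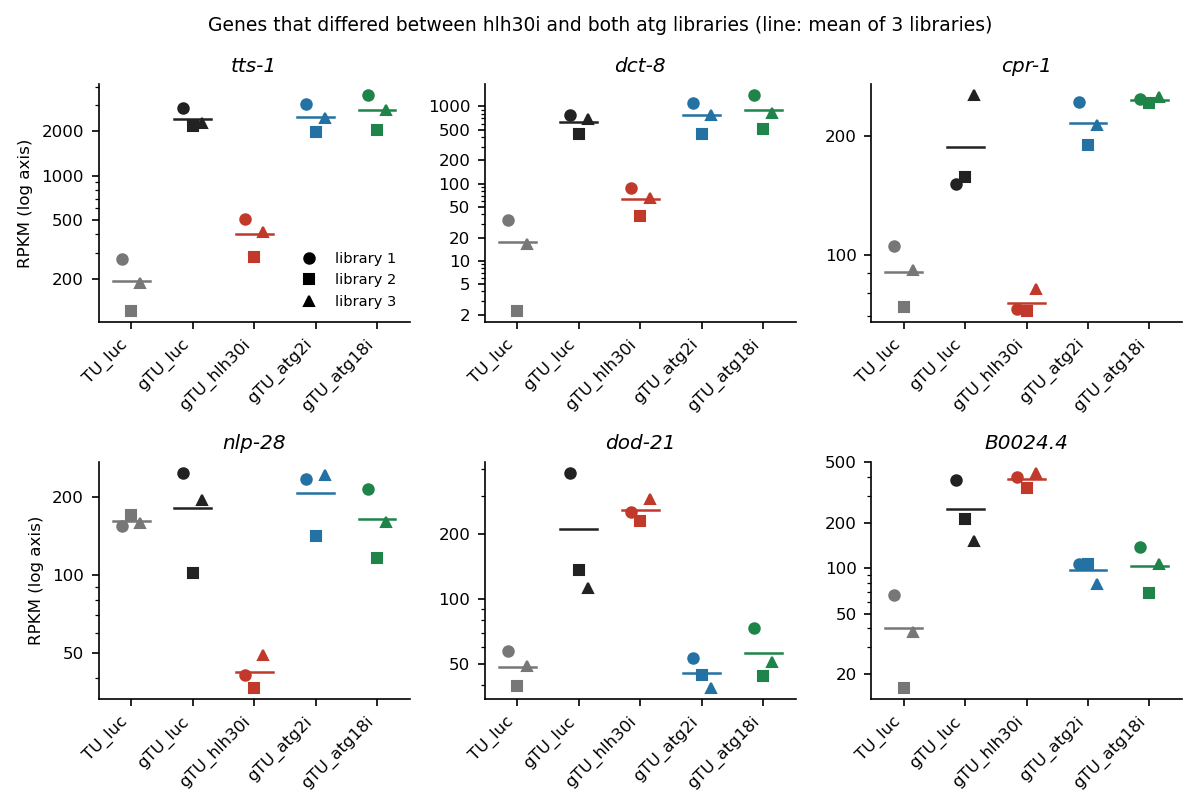
RPKM of tts-1, dct-8, cpr-1, nlp-28, dod-21 and B0024.4 in each of the 15 libraries by group, on log axes. cpr-1 was at 75.8 ± 5.53 in the libraries labelled hlh-30 RNAi, 215 ± 26.7 for atg-2 RNAi and 246 ± 4.66 for atg-18 RNAi, and dod-21 at 259 ± 30.2, 45.7 ± 7.44 and 56.5 ± 15.4, against 113 to 386 in the glp-1 luc libraries.

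The 3 RNAi comparisons share the glp-1 luc libraries, so their overlap was set against 100 simulations of unchanged groups. There the deviations of the 12 glp-1 libraries were drawn in random order and with random sign. Correlations between same-numbered libraries were thus not kept, and germline RNA of the libraries numbered 1 entered as spread. The simulated ranges are wide and can exclude little. Limma called 0 genes for atg-2 and for atg-18 RNAi, so no call could be shared. At an unadjusted p under 0.05, hlh-30 and atg-2 RNAi shared 75 higher and 113 lower genes, hlh-30 and atg-18 RNAi 85 and 125, and atg-2 and atg-18 RNAi 120 and 270, against 11.3 and 37.3, 12.5 and 29.1, and 8.22 and 26.7 for independent lists. Simulations without any effect shared 75.2 higher genes on average (95% range 0 to 399.5) and 87.2 lower genes (0 to 809). The covariance of fold changes was 0.0222, 0.0283 and 0.0310 for the 3 pairs, against 0.0271 in simulation (-0.000514 to 0.0648), and Pearson's r across genes, which are not independent replicates, was 0.382, 0.486 and 0.596 against 0.498 (0.00454 to 0.816). With 3 control libraries the controls cannot be split, and part of the excess over independent lists may come from them.

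Whether RNAi moved genes back toward the TU3401 level was read from the same fits. Across genes the covariance of the RNAi change with the glp-1 change was -0.0399 for hlh-30 RNAi, -0.0884 for atg-2 RNAi and -0.000325 for atg-18 RNAi, each inside the range of the simulations (mean -0.0213, 95% range -0.234 to 0.133). Genes at an unadjusted p under 0.05 moved opposite to the glp-1 change in 54.2%, 68.9% and 60.4% of cases, against 53.8% in simulation (29.8% to 75.5%).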

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

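Limma without the trend, voom on recovered reads, the minimum of 10 reads, the genes without germline-linked ones, the libraries numbered 1 left out and all settings for lists in the direct contrasts were chosen after seeing the data, and all other settings before. Of the values recomputed for named genes under all settings, 1894 kept their direction and side of the threshold, 298 kept the direction but no longer passed, 11 newly passed and 50 changed sign; for gene lists these were 588 that stayed, 215 that no longer passed and 8 that changed sign. Of the counts of changed genes 77 stayed within 1.5 times and 50 did not. Unless the setting itself leaves out genes or libraries, the cause was not tested. The tests planned for count tables (edgeR as the main test, DESeq2 as an alternative) were not run, and the recovered reads were tested with voom only. Depth limits short and low genes most: a single read is worth 1.86 to 2.72 RPKM in a gene of 21 bases.

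With an estimated correlation 0 lists passed in the 4 comparisons or the 3 direct contrasts, and with fry 0 passed for hlh-30, atg-2 or atg-18 RNAi or in the direct contrasts. Scaled on neuronal and muscle genes, the glp-1 changes turned negative for atg-2 (-0.16), dnj-20 (-0.84), dnj-7 (-0.91), hlh-30 (-0.35), ldh-1 (-0.88), nas-37 (-0.019), perm-2 (-0.24), perm-4 (-0.067), rpl-11.2 (-0.17), sid-1 (-1.02), sqst-1 (-0.27), ucr-2.1 (-0.13) and vit-2 (-0.072). So did glp-1 for hlh-30 RNAi (-0.038), hlh-30 for atg-2 RNAi (-0.031) and atg-18 for atg-18 RNAi (-0.015), none of which had passed. This scaling left 5 genes for hlh-30 RNAi and 4 lists for atg-18 RNAi, and turned the ribosome list there (0.142). The muscle list is part of this scaling, so its loss follows from the setting. The other list calls that it ended for RNAi groups are given with those lists.

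For hlh-30 RNAi limma called 7 genes at an absolute log2 change of at least 1, 56 with 15 libraries in the fit, 2 without a filter, 4 without the trend and 1 without the libraries numbered 1. For atg-2 RNAi it called 2 with 15 libraries and 1 without the trend, and for atg-18 RNAi 3 with 15 libraries, 1 without the trend and 2 with voom. Between hlh-30 and atg-2 RNAi 52 genes were called without a filter and 70 without the trend. Between hlh-30 and atg-18 RNAi there were 46 with only the 2 groups in the fit, 59 without a filter, 50 without the trend and 67 without the libraries numbered 1. Between atg-2 and atg-18 RNAi there were 0 with only the 2 groups, 1 without germline-linked genes and 0 without the libraries numbered 1, and mxl-2 was at 0.0049 with voom.

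With the replicate number as a block, limma called 46 genes for hlh-30 RNAi and 0 for each of atg-2 and atg-18 RNAi, and 757, 506 and 1 in the direct contrasts of hlh-30 with atg-2, hlh-30 with atg-18 and atg-2 with atg-18 RNAi. On recovered reads with the block, voom called 399, 596 and 457 genes against luc and 1135, 837 and 99 in the direct contrasts. By the bound of 0.1 the numbers were taken to pair samples for atg-2 RNAi with luc and in the 3 direct contrasts. Elsewhere same-numbered libraries correlated across genes at 0.0707, 0.0722 and -0.0238 for glp-1 against TU3401, at 0.358, 0.241 and 0.0690 for hlh-30 RNAi and at 0.231, 0.214 and 0.0841 for atg-18 RNAi. Each library correlated best with its own number for atg-2 and atg-18 RNAi with luc and in the direct contrasts, but not for hlh-30 RNAi with luc or for TU3401. When 1 pair was flipped, the block gave 0 genes on log2 RPKM. With voom a flip gave 12 genes once for atg-2 RNAi with luc, 17, 17 and 16 between hlh-30 and atg-18 RNAi, 67, 58 and 52 between atg-2 and atg-18 RNAi, and otherwise 0. The block ended the insulin call for atg-18 RNAi (0.0970), and for hlh-30 RNAi endoplasmic reticulum chaperones, regulators of germline loss and oocyte genes passed with it (0.0113, 0.0154 and 0.0154). With the block and an estimated correlation the hlh-30 RNAi lists did not pass camera (adjusted p = 0.903, 0.546 and 0.903). Where the numbers pair, the block changed the calls printed beside the results and no other call of a named gene over all genes or of a list in camera.

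The covariance with the glp-1 change was -0.0165, -0.0495 and -0.0201 for hlh-30, atg-2 and atg-18 RNAi among genes with a mean RPKM of at least 5, and -0.0204, -0.0203 and -0.0215 without germline-linked genes. With voom the observed covariance was -0.0767 for hlh-30 RNAi and 0.0197 for atg-18 RNAi. Without the libraries numbered 1 it was -0.0282 for atg-2 RNAi and -0.0620 for atg-18 RNAi. Leaving out 1 glp-1 luc library at a time gave -0.0968 to -0.0244, -0.155 to -0.0695 and -0.0427 to 0.00997.

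Leaving out 1 library at a time gave, for glp-1 against TU3401, mml-1 at -0.17 to 0.062. For hlh-30 RNAi it gave 0 to 11 genes, glp-1 at -0.15 to 0.12, sid-1 at -0.078 to 0.043, and camera p-values of 3.46e-05 to 0.913 for the respiratory chain and 6.54e-11 to 0.981 for ribosomal genes. For atg-2 RNAi it gave atg-18 at -0.078 to 0.033, glp-1 at -0.13 to 0.22, hlh-30 at -0.040 to 0.12, mml-1 at -0.18 to 0.055, the cell cycle at 5.32e-05 to 0.263 and oocyte genes at 0.000353 to 0.292. For atg-18 RNAi it gave 5 to 15 lists, atg-18 at -0.19 to 0.42, glp-1 at -0.098 to 0.058, hlh-30 at -0.12 to 0.078, mxl-2 at -0.19 to 0.024, sid-1 at -0.14 to 0.0027 and ribosomal genes at 6.08e-13 to 0.856. Between hlh-30 and atg-2 RNAi there were 30 to 86 genes, with glp-1 at -0.21 to 0.16. Between hlh-30 and atg-18 RNAi there were 28 to 78 genes, with atg-2 at -0.16 to 0.17, glp-1 at -0.13 to 0.14 and sid-1 at -0.0026 to 0.10. Between atg-2 and atg-18 RNAi there were 0 to 2 genes, with atg-18 at -0.46 to 0.15, glp-1 at -0.11 to 0.24, hlh-30 at -0.039 to 0.16, mxl-2 at -0.12 to 0.088 and the ribosome list at 7.77e-10 to 0.391 in camera, pointing down without atg-18 RNAi library 1.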

Other observations

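All tests of explanations here, the splits of libraries and the gene families were chosen after the result was seen. Families are here sets of genes with the same symbol prefix, whether or not their sequences are related. Of 70 families with at least 15 tested genes, at least 80% of members rose in 15 and fell in 18 between TU3401 and glp-1 worms on luc. These counts are by limma over all genes on the RPKM scale, and were not made under scaling on neuronal and muscle genes. The other 37 lay under this share in either direction, and some of them went both ways on the RPKM scale, such as unc (38 rose and 32 fell of 88), pqn (18 and 20 of 42), daf (8 and 9 of 20) and kin (9 and 10 of 19). Scaled on neuronal and muscle genes, these families mostly fell. There 6 unc genes rose and 62 fell, with 4 and 25 for pqn, 2 and 15 for daf and 2 and 11 for kin. No enrichment of families was tested, and those named below were picked after their values were seen. In whole-worm RNA a fall of a family cannot be told apart from the loss of the germline's own RNA. Nuclear pore genes (npp) fell in 26 of 26 cases (median -3.18, -4.53 scaled on neuronal and muscle genes), mitochondrial ribosome genes in 40 of 40 (mrpl; -1.90, -3.33 scaled) and 29 of 29 (mrps; -1.97, -3.34 scaled). Translation initiation factors (eif) fell in 23 of 23 (-1.77, -3.22 scaled), and the general transcription genes mdt and taf in 21 of 21 and 17 of 17 (-2.48 and -2.58; -3.86 and -3.84 scaled). In the F-box and BATH families, fbxb genes fell in 73 of 73 cases (-2.21, -2.89 scaled) and bath genes in 28 of 30 (-2.92, -3.74 scaled). As many genes of each of these 8 families fell when scaled, while fbxa genes rose in 67 of 99 (1.03), but when scaled 20 rose and 34 fell (-0.025).

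In the other direction, counts depended on the scale, and those that rose and fell under scaling on neuronal and muscle genes stand second. Carboxylesterases (cest) rose in 27 of 28 cases (median 1.83, 0.56 scaled with 16 and 2), saposin-like genes (spp) in 20 of 21 (1.70, 0.36 scaled with 11 and 4), transthyretin-related genes (ttr) in 43 of 49 (1.60, 0.18 scaled with 21 and 10) and C-type lectins (clec) in 76 of 96 (1.37, 0.35 scaled with 42 and 21). Of the detoxifying enzymes, cytochromes P450 (cyp) rose in 41 of 49 cases (1.49, 0.45 scaled with 23 and 10), UDP-glucuronosyltransferases (ugt) in 46 of 53 (1.48, 0.20 scaled with 24 and 8) and glutathione transferases (gst) in 27 of 35 (1.24, 0.038 scaled with 13 and 8). The neuropeptide families flp and nlp rose in 30 of 30 and 55 of 66 (1.76 and 1.45; 0.33 and 0.13 scaled, with 14 and 1 and with 12 and 10). Nuclear hormone receptors (nhr) rose in 129 of 168 (0.90), neuropeptide receptors (npr) in 20 of 22 (0.93), potassium channels (twk) in 22 of 26 (1.07) and vacuolar ATPase genes (vha) in 18 of 20 (0.54), but the medians of these 4 families turned to -0.13, -0.073, -0.057 and -0.93 when scaled, with 21 and 61, 2 and 1, 4 and 4, and 0 and 18 genes that rose and fell.

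No RNAi target was lower on average in the libraries labelled with its RNAi. For hlh-30 the lowest such library was 2.303 times the highest glp-1 luc library, which a knockdown confined to neurons would not give by itself. Reads from another source could hide a fall in neurons, so such a knockdown stays open. For atg-2 and atg-18 it was not tested. An exchange of a single library with another glp-1 library is argued against for hlh-30 and atg-2 RNAi. The test used genes with at least 10 mean reads. There dct-7 set the 3 hlh-30 RNAi libraries apart from the other 9 by 5.371-fold in RPKM + 1. F23A7.5 did so for atg-2 RNAi by 7.506-fold, and hmp-2 for atg-18 RNAi by 1.741-fold. Triples with 1 library exchanged reached up to 1.62-fold (5.08-fold without that minimum, from a 21-base gene of at most 3 reads). For atg-18 RNAi an exchange is argued against only with the minimum, which was set after the values were seen. Without it, 5 of its 27 exchanged triples were set apart as far, by up to 2.88-fold. A wrong label of the whole group was judged on the target's own gap. For hlh-30 this gap was 2.27-fold, but upward, opposite to a knockdown. It argues against a wrong label only if the RNAi treatment itself raised the hlh-30 reads, which stays open. A wrong label also stays open for atg-2 (1.094-fold) and for atg-18 (0.626-fold, an overlap, with its neighbour F41E6.12 at 1.75-fold). Reads from the double-stranded RNA of the feeding clone may have been counted as the target: hlh-30 varied between its RNAi libraries more than 100% of genes of similar level, and atg-18 more than 99.2%, which such carried-in RNA could give, while for atg-2 the share was 49.3%, so that it cannot be told apart from an unchanged level. A rise of the worm's own transcript was not tested and stays open, because RPKM per gene holds no position within the gene.

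Germline RNA stood higher in libraries 1 of glp-1 luc, hlh-30 RNAi and atg-2 RNAi (1.03%, 1.64% and 2.59% of TU3401) than in the other 9 glp-1 libraries. A few worms with a germline in the sample may be the source, since oocyte and germline core genes then come at 1 share. The median of the other 9 glp-1 libraries was first subtracted from each share. The ratio of what remained, oocyte over germline core, was 1.495, 0.982 and 1.07. Greater depth is argued against, since 1 of the 3 libraries was deeper than the deepest of the other 9. Whether the sample held such worms cannot be read from these values.

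Of the 11 genes called for hlh-30 RNAi, 21ur-1893 and 21ur-784 are 21-base piRNA genes. Their values may follow from gene length, since a single read is worth 1.86 to 2.72 RPKM there: the highest count in 1 library over these genes was 2 reads. With at least 10 mean reads, 13 genes were called. No biological explanation was tested.

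Splits of the same 6 libraries number 10 for each comparison, too few for a share under 0.05. The real split and the highest other gave 12175 and 0 changed genes for glp-1 against TU3401, 11 and 4 for hlh-30 RNAi, 0 and 1 for atg-2 RNAi and 0 and 7 for atg-18 RNAi. In the direct contrasts they gave 126 and 0 (hlh-30 against atg-2 RNAi), 127 and 0 (hlh-30 against atg-18 RNAi) and 2 and 0 (atg-2 against atg-18 RNAi). For gene lists in camera they gave 21 and 23, 7 and 15, 14 and 16, and 9 and 12, in the order of the 4 comparisons with luc. As many genes as in the real split came in 1 split of the 10 for glp-1, for hlh-30 RNAi and for each direct contrast, and in 10 for atg-2 and atg-18 RNAi; as many lists came in 4, 5, 4 and 5. Where the numbers pair the libraries (atg-2 RNAi with luc and the direct contrasts), the 3 other splits that part all 3 pairs gave 0 genes, and for atg-2 RNAi 8, 6 and 0 lists against 14, while the splits with 15 or 16 lists part 1 pair.

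F23A7.5 was at 26.6, 95.5 and 370.4 RPKM in the libraries labelled atg-2 RNAi and at 1.88 to 2.68 in the other glp-1 libraries. Whether carried-in RNA of a feeding clone was counted there, as asked above for the RNAi targets, was not tested. H02F09.3 was at 7.93, 4.07 and 4.09 in the glp-1 luc libraries and at 1.37 to 1.89 in the 6 libraries labelled atg-2 or atg-18 RNAi.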
